A study of Homo sapiens with 8 samples.

How the data were processed

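Expression was measured in A673 cells, an Ewing's sarcoma cell line, on 8 Affymetrix oligonucleotide arrays of 1 colour, hybridised with biotin-labelled material from total RNA. Per the labels, 4 arrays carried RNA from cells with the construct luc-RNAi (replicates 1, 3, 5 and 7), 2 from cells with EF-2-RNAi (replicates 2 and 4) and 2 from cells with EF-4-RNAi (replicates 6 and 8). The series design counts EF-2-RNAi and EF-4-RNAi as EWS/FLI knockdown constructs. Each array was taken as 1 replicate. No source used here says that the replicates came from separate cultures, so all p-values measure the spread between these samples, which may be technical.

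The deposited values are intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version of MAS5, its background and scaling settings and the scanner are not given in the sources used here, and detection calls were not used here. Every array of the deposited intensity table had a mean of 173.24 over its 22283 probe sets. On every array, all 400 low values checked were whole multiples of 1 step, within a tolerance of 0.02 of a step, and the step was 0.1 on EF-4-RNAi replicate 8 alone. If the other arrays had been scaled to that array's mean, which no source used here states, the steps would give the factors, from 0.712 for luc-RNAi replicate 1 to 1.23 for EF-2-RNAi replicate 2. Scaling to a common mean fixes the mean of each array, so a change of total messenger RNA per cell cannot be read from these values. For arrays there is no read depth, and the number of arrays limits the precision.

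Of the 22283 probe sets, 68 were Affymetrix controls and were left out of all tests. Among the other 22215 probe sets, the annotation table gave 1 gene symbol for 19065, several for 1043 and none here for 2107. Symbols were updated through an NCBI RefSeq gene table of assembly GRCh38.p14, used for names only, which matched 19053 probe sets. No gene was named from a probe set with several symbols, and no genomic coordinates are given because no genome was used here. Gene names rest on a platform annotation that can be old.

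Values were analysed as log2(intensity + 4.05), where the pseudocount 4.05 is the 10th percentile of all values, with no further normalization between arrays. Log2 changes of genes with low intensity are understated on this scale. A probe set was tested if it exceeded 29.0, the 40th percentile of all values, on at least 2 arrays, which kept 15445 probe sets. Tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 15445 probe sets and a threshold of 0.05, and every adjusted p for a gene or probe set comes from limma. For knockdown against luc-RNAi the 8 arrays formed 2 arms of 4, so that the difference between the constructs counted as spread. For each construct against luc-RNAi, and for EF-4-RNAi against EF-2-RNAi, the 8 arrays formed 3 groups with 1 shared estimate of the spread. Residual degrees of freedom were 6 and 5, and eBayes added 6.58 and 8.91 prior degrees of freedom.

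Each gene was represented by its brightest tested probe set with 1 symbol, and by one ending in _x_at only where it had no other, which gave 9239 genes. Where a gene had several called probe sets (261 genes), no gene was called in both directions. The 33 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. The test was repeated with a correlation estimated for each list. The lists of EWS/FLI-activated and EWS/FLI-repressed genes come from the literature, partly from studies of this cell line, and are not independent evidence of a direction. The other lists cover cell cycle, matrix, cytoskeleton, signalling, lineage, stress, immune, ribosome, chromatin, lysosome and reference genes, and markers of epithelial, haematopoietic and endothelial cells.

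Genes were named by a rule fixed before the data were examined. It took FLI1 and EWSR1, and the 10 largest rises and 10 largest falls among genes called in knockdown against luc-RNAi whose 4 knockdown arrays all lay on one side of the 4 luc-RNAi arrays. It also took the 5 largest differences in each direction between EF-4-RNAi and EF-2-RNAi, up to 4 called members of each list with the largest change (where none was called, the 2 with the smallest p), and 14 targets of EWS/FLI known from the literature. Of these 14, 13 were tested. NR0B1 was not named alone by a probe set in the annotation used here and was not analysed here. The rule gave 126 genes. Genes named outside it are identified as chosen after their values were seen.

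Both constructs were compared with the same 4 luc-RNAi arrays. The overlap of their calls was therefore set beside 100 draws in which all 8 arrays, luc-RNAi included, were simulated with no effect. It was also set beside the overlap of independent lists and beside 6 splits that gave each construct its own 2 luc-RNAi arrays. Signal from ribosomal RNA was read from 6 control probe sets for 18S and 28S RNA, and RNA integrity from the 3' to 5' ratios of the GAPDH and ACTB control probe sets, compared by two-sided exact permutation tests over 70 regroupings. All 35 splits of the 8 arrays into 4 and 4 were also tested. Alternatives fixed in advance were a smaller and a larger pseudocount, no filter and a stricter filter (64.7, the 60th percentile), quantile normalization, scaling to the same median and no intensity trend. Others fixed in advance were 3 groups in place of 2 arms, consecutive title numbers as a block, the mean of a gene's probe sets, an estimated correlation for lists, and leaving out each array in turn. Alternatives added after the data had been examined used the ribosomal signal or the GAPDH ratio as a covariate, the high and low ribosomal arrays as a block, or the arrays with low ribosomal signal alone.

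The tests were checked on simulated data with 200 changed probe sets among 15445. In the data 1865 probe sets were called in knockdown against luc-RNAi, and with more calls the adjustment is less strict. The shares below therefore hold for the simulated setting and do not give the sensitivity of the tests on the data. For knockdown against luc-RNAi, 29.9% of changes of 1 log2 unit and 72.7% of changes of 2 were called, none of those of 0.5 were, and 5 of the 73 calls were unchanged probe sets. For EF-2-RNAi against luc-RNAi these shares were 26.9% and 71.2%, with 6 unchanged among 71 calls. For EF-4-RNAi against luc-RNAi they were 34.3% and 81.8%, with 6 unchanged among 83 calls. For EF-4-RNAi against EF-2-RNAi, 1.49%, 13.4% and 57.6% of changes of 0.5, 1 and 2 log2 units were called, with 0 unchanged among 48 calls. In 50 simulated draws over 9239 genes, camera called 98% of lists shifted by 0.5 log2 units and 2 unshifted lists, with genes drawn independently, which real genes are not.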

Results

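Gene expression was compared between A673 cells carrying luc-RNAi and A673 cells in which EWS/FLI was targeted by 1 of 2 RNA interference constructs, EF-2-RNAi and EF-4-RNAi. A673 is an Ewing's sarcoma cell line, and EWS/FLI is the fusion oncoprotein of this tumour, which joins the amino-terminal part of EWSR1 to the DNA-binding part of the transcription factor FLI1. There were 4 luc-RNAi arrays, 2 EF-2-RNAi arrays and 2 EF-4-RNAi arrays. All arrays had the same mean intensity, and their median intensities lay between 38.1 and 47.2. Across the 15445 tested probe sets, log2 values correlated with r between 0.928 and 0.951 within a group, 0.878 and 0.917 between EF-4-RNAi and luc-RNAi, and 0.825 and 0.848 between EF-2-RNAi and luc-RNAi (probe sets are not independent replicates). Between EF-2-RNAi and EF-4-RNAi r lay between 0.886 and 0.913. For EF-4-RNAi replicate 6, r was 0.892 to 0.917 with luc-RNAi arrays and 0.886 and 0.889 with EF-2-RNAi arrays. For EF-4-RNAi replicate 8, r was 0.878 to 0.897 with luc-RNAi arrays and 0.9035 and 0.913 with EF-2-RNAi arrays. The first principal component held 44.7% of the variance. On it the luc-RNAi arrays lay between -43.0 and -35.3, the EF-4-RNAi arrays at 6.15 and 24.9, and the EF-2-RNAi arrays at 62.9 and 64.9. Signal on the control probe sets for ribosomal RNA split the arrays across the groups, with a mean of 443 on luc-RNAi replicate 3, 434 on luc-RNAi replicate 5 and 211 on EF-4-RNAi replicate 6, against 34.0 to 64.6 on the other 5 arrays. The log2 ratio of 3' to 5' signal was higher by 0.25 for GAPDH and 0.23 for ACTB in knockdown arrays, each with an exact permutation p of 0.229 (adjusted p = 0.343 over 3 measures, smallest possible p 0.0286).

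FLI1 signal was lower in all knockdown arrays. FLI1 had 3 probe sets, whose sequence can be shared by the fusion and the native transcript. Which of these transcripts they read was not examined. Probe set 204236_at fell from 98.5 ± 27.0 in luc-RNAi to 17.9 ± 8.37 in knockdown (intensity, SD, n = 4 each), a log2 change of -2.24 ± 0.31 (SE, adjusted p = 0.000604). Probe set 210786_s_at fell from 264 ± 114 to 54.8 ± 11.4 (log2 change -2.10 ± 0.29, adjusted p = 0.000595). Probe set 211825_s_at fell from 140.4 ± 29.5 to 43.2 ± 18.7 (log2 change -1.67 ± 0.28, adjusted p = 0.00214). All 3 were also called for each construct alone, with log2 changes of -2.48, -2.33 and -1.84 for EF-2-RNAi and -2.01, -1.87 and -1.51 for EF-4-RNAi. The difference between the constructs did not pass the test at any of them, with log2 values for EF-4-RNAi minus EF-2-RNAi of 0.47, 0.46 and 0.32 (adjusted p = 0.626, 0.575 and 0.732). EWSR1, which encodes an RNA-binding protein, fell less, from 417 ± 35.3 to 300.3 ± 21.5 at probe set 209214_s_at (log2 change -0.47 ± 0.13, adjusted p = 0.0354). That call was lost without luc-RNAi replicate 3, 5 or 7 or EF-2-RNAi replicate 2 or 4 (adjusted p up to 0.116). It was also lost with arrays scaled to the same median, no intensity trend, the mean of its probe sets or any adjustment for ribosomal signal or the GAPDH ratio (adjusted p from 0.0568 to 0.0809), and on the low-ribosomal arrays (-0.38, adjusted p = 0.309). A second EWSR1 probe set, 210011_s_at, had a log2 difference of -0.33 ± 0.16 and was not called (adjusted p = 0.224). Probe set 210012_s_at lay below the filter at 1.65 ± 0.466 and 2.86 ± 2.91.

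With EWS/FLI targeted, CXCL8, which encodes the chemokine interleukin-8, had the largest log2 rise. It rose from 6.14 ± 4.01 in luc-RNAi to 611 ± 249 in knockdown (intensity, SD, n = 4 each), a log2 change of 5.86 ± 0.35 (SE, adjusted p = 2.43e-06). Among the insulin-like growth factor binding proteins, IGFBP5 rose from 19.7 ± 7.81 to 1416 ± 642 (log2 change 5.83 ± 0.33, adjusted p = 2.11e-06), and IGFBP3 from 38.2 ± 12.2 to 2452 ± 2035 (5.38 ± 0.57, adjusted p = 0.000109). IGFBP7 rose from 3.72 ± 0.406 to 801 ± 724 (5.26 ± 1.18, adjusted p = 0.0121). The other largest rises were those of DKK3, of the Dickkopf family of secreted proteins (5.17 ± 0.62), CD9, a tetraspanin (5.06 ± 0.56), and SPP1, which encodes osteopontin (4.80 ± 0.51). Next came PTX3, a secreted pentraxin (4.41 ± 0.34), COL6A2, a chain of type VI collagen (4.41 ± 0.54), and NT5E, the ecto-5'-nucleotidase CD73 (4.24 ± 0.26). Adjusted p for these 6 lay between 2.91e-06 and 0.000285. PPP1R1A, which encodes a regulatory inhibitor of protein phosphatase 1, had the largest log2 fall, from 219.6 ± 72.7 to 2.79 ± 1.34 (-4.98 ± 0.32, adjusted p = 2.94e-06). Means below the filter of 29.0, such as this one and those of CXCL8, IGFBP5 and IGFBP7 in luc-RNAi, make the size and order of these changes depend on the pseudocount. FCGRT, the neonatal Fc receptor, fell from 327 ± 89.7 to 14.9 ± 8.04 (-4.18 ± 0.30, adjusted p = 1.11e-05). The other largest falls were those of DAB1, an adaptor of reelin signalling (-3.47 ± 0.48), NPY1R, a neuropeptide Y receptor (-3.23 ± 0.48), CDH12, a cadherin (-2.93 ± 0.46), and GSTM4, a glutathione transferase (-2.78 ± 0.28). They also included MYOM2, a sarcomere protein (-2.74 ± 0.52), TENM1, a teneurin (-2.66 ± 0.52), C7, a complement component (-2.65 ± 0.39), and SLC24A3, a sodium, potassium and calcium exchanger (-2.56 ± 0.53). Adjusted p for these 8 lay between 8.47e-05 and 0.00759. In each of these 20 genes all 4 knockdown arrays lay on one side of all 4 luc-RNAi arrays, as the rule for naming them requires, and all kept their call when any 1 array was left out. With the arrays of low ribosomal signal alone, C7 had a value of -2.19 and was not called (adjusted p = 0.0815). Without an intensity trend IGFBP7 was not called (adjusted p = 0.0505).

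**Figure D1:**
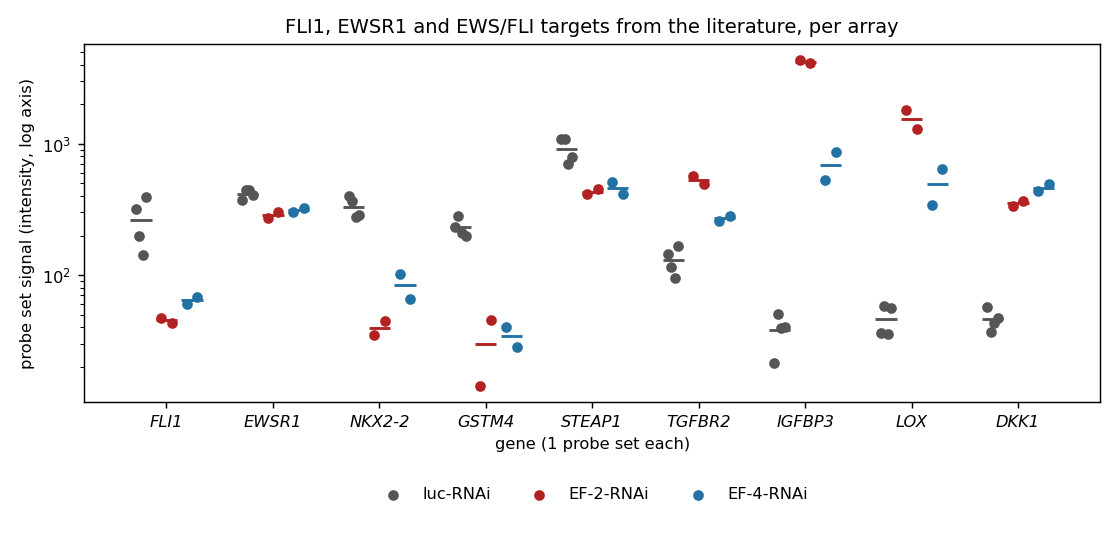
Signal (intensity, log axis) of 1 probe set each for FLI1, EWSR1 and 7 EWS/FLI targets from the literature on the 8 arrays, with points for arrays and lines for group means. In luc-RNAi the mean for FLI1 was 264, against 45.4 in EF-2-RNAi and 64.2 in EF-4-RNAi, and for IGFBP3 the means were 38.2, 4209 and 695.

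Of the 15445 probe sets, 1865 were called in knockdown against luc-RNAi, 1166 higher and 699 lower, and 726 of the higher and 238 of the lower ones changed at least 2-fold. By gene, 767 of 9239 rose and 423 fell. Of 1898 tested probe sets with no single gene symbol here, 170 were called. Within the 5 arrays of low ribosomal signal (2 luc-RNAi, 3 knockdown) 1034 probe sets were called, 752 higher and 282 lower. The only EF-4-RNAi array among them is replicate 8, so values for EF-4-RNAi on the low-ribosomal arrays rest on it alone. Called within the 3 of high signal (2 luc-RNAi, 1 knockdown) were 395, 235 higher and 160 lower, where the knockdown arm is EF-4-RNAi replicate 6 alone and only the luc-RNAi pair gives a spread. Without luc-RNAi replicate 3, 1144 were called and only 325 of them lower. The number of lower calls was 423, 441 and 451 without luc-RNAi replicate 1, luc-RNAi replicate 7 and EF-2-RNAi replicate 4.

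Genes known from the literature to be activated by EWS/FLI were lower in knockdown. Of 38 tested members of that list, 15 fell and 1 rose, with a median log2 change of -0.84. Adjusted over the list alone, 20 fell and 1 rose. Camera's adjusted p was 2.17e-11 with the preset correlation, and the call was lost (adjusted p = 0.0834) with an estimated correlation. NKX2-2, a homeobox transcription factor, fell from 333 ± 58.7 to 61.9 ± 29.4 (SD, n = 4 each; log2 change -2.44 ± 0.27, adjusted p = 0.000152). GSTM4 fell from 230.5 ± 36.8 to 32.1 ± 13.7 (adjusted p = 8.47e-05). STEAP1, a protein of the cell surface, fell from 917 ± 201 to 447 ± 48.4 (-1.01 ± 0.16, adjusted p = 0.00187). CAV1, which encodes caveolin-1, fell by 0.75 (adjusted p = 0.0185). Its call was lost without EF-2-RNAi replicate 4 (adjusted p = 0.052) or luc-RNAi replicate 5 (adjusted p = 0.0559), without an intensity trend (adjusted p = 0.0753) and on the 5 low-ribosomal arrays (-0.85, adjusted p = 0.0538). The member that rose was UPP1, which encodes uridine phosphorylase (1.58 ± 0.24, adjusted p = 0.00134, chosen after its value was seen). CCND1, the cyclin D1 gene, stood at 1586 ± 271 and 1694 ± 195 and was not called (adjusted p = 0.706). Its sign turned to -0.034 with the mean of its probe sets and to -0.067 on the low-ribosomal arrays. Log2 differences of -0.65 ± 0.35 for MYC (adjusted p = 0.271) and -0.50 ± 0.17 for EZH2, a histone methyltransferase (adjusted p = 0.0789), were not called either. MYC passed without EF-4-RNAi replicate 6 (-1.03, adjusted p = 0.0175), on the low-ribosomal arrays (-1.25, adjusted p = 0.0412) and with 3 groups (adjusted p = 0.0426). For EF-2-RNAi alone MYC was called (-1.34 ± 0.25, adjusted p = 0.00179), and for EF-4-RNAi it was not (0.04 ± 0.25, adjusted p = 0.96). The EF-4-RNAi value turned to -0.41 without EF-4-RNAi replicate 6, -0.10 without luc-RNAi replicate 5 and -0.63 on the low-ribosomal arrays. EZH2 passed with 3 groups (adjusted p = 0.0497) and quantile normalization (-0.53, adjusted p = 0.0462).

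Genes known from the literature to be repressed by EWS/FLI were higher in knockdown. Of 28 tested members, 18 rose and 0 fell, with a median log2 change of 1.54. Adjusted over the list alone, 19 rose and 1 fell. The list was called with the preset correlation (adjusted p = 4.13e-19) and with an estimated correlation (adjusted p = 0.0435). Both literature lists come partly from studies of this cell line and are not independent evidence. LOX, the lysyl oxidase gene, rose from 46.5 ± 12.4 to 1019.8 ± 651 (SD, n = 4 each; log2 change 4.11 ± 0.41, adjusted p = 7.84e-05). DKK1, a secreted inhibitor of Wnt signalling, rose from 46.2 ± 8.44 to 408 ± 69.3 (3.03 ± 0.18, adjusted p = 2.43e-06). TGFBR2, a receptor of transforming growth factor beta (TGF-beta), rose from 130.1 ± 31.6 to 402 ± 156 (1.55 ± 0.26, adjusted p = 0.00251). CDKN1A, the cell cycle inhibitor p21, rose from 59.9 ± 10.7 to 189 ± 46.4 (1.58 ± 0.21, adjusted p = 0.00044). FOXO1, a forkhead transcription factor, had a log2 difference of 0.73 ± 0.34 and was not called (adjusted p = 0.197). It was called for EF-4-RNAi alone (1.25 ± 0.33, adjusted p = 0.0291) and not for EF-2-RNAi (0.20 ± 0.33, adjusted p = 0.75). That call was lost without EF-4-RNAi replicate 6 (adjusted p = 0.175) or 8 (0.161), with no filter (0.068), without an intensity trend (0.0621) and with the mean of its probe sets (0.39, adjusted p = 0.464). On the low-ribosomal arrays (1.37, adjusted p = 0.205) and with the GAPDH covariate (0.106) it was lost too. The EF-2-RNAi value turned to -0.21 with the mean of its probe sets and to -0.0049 without luc-RNAi replicate 7.

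The lists of matrix, adhesion, TGF-beta and insulin-like growth factor axis genes were higher in knockdown. Among collagens and other extracellular matrix genes, 27 of 41 tested members rose and 1 fell, with a median log2 change of 1.54 (adjusted p = 4.13e-19, and adjusted p = 0.112 with an estimated correlation, which ends the call). Adjusted over the list alone, 30 rose and 2 fell. MGP, the matrix Gla protein, rose from 3.10 ± 2.07 to 139 ± 102 (SD, n = 4 each; log2 change 4.12 ± 0.47). LOXL2, a lysyl oxidase, rose from 52.7 ± 16.8 to 1083 ± 622 (4.05 ± 0.43). FBLN5, an elastic fibre protein, was the member that fell (-1.57 ± 0.20, adjusted p = 0.000369, chosen after its value was seen). In the list of actin cytoskeleton and focal adhesion genes 18 of 38 rose and 1 fell, with a median of 0.78 (adjusted p = 1.8e-10, and adjusted p = 0.124 with an estimated correlation). Adjusted over the list alone, 20 rose and 2 fell. Its largest changes were in the integrin chains ITGA3 (2.96 ± 0.61), ITGA6 (2.32 ± 0.40) and ITGA4 (2.18 ± 0.35). CNN2, a calponin, fell (-0.51 ± 0.13, chosen after its value was seen). Of the TGF-beta pathway and its immediate targets, 8 of 26 rose and 0 fell (adjusted over the list alone 10 and 0), with a median of 0.40 (adjusted p = 8.48e-05, and adjusted p = 0.0834 with an estimated correlation). They included TGFBI, a secreted matrix protein, at 399 ± 117 and 3519 ± 1165 (3.11 ± 0.25), and CCN2, the connective tissue growth factor gene (1.92 ± 0.24). In the insulin-like growth factor axis 5 of 16 members rose and 1 fell (adjusted over the list alone 5 and 3), with a median of 0.47 (adjusted p = 0.0209, and adjusted p = 0.137 with an estimated correlation). The 5 were the binding proteins IGFBP2 (0.59 ± 0.12, chosen after its value was seen), IGFBP3, IGFBP5, IGFBP6 (1.48 ± 0.32) and IGFBP7. IRS2, an insulin receptor substrate, fell (-1.11 ± 0.27, likewise chosen afterwards).

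Genes of proliferation, ribosome assembly and chromatin were lower, by smaller amounts. In the list for G1/S and DNA replication 6 of 40 tested members fell and 0 rose (adjusted over the list alone 12 and 0), with a median log2 change of -0.34 (adjusted p = 2.07e-06, and adjusted p = 0.14 with an estimated correlation). PRIM1, the DNA primase subunit, fell from 336 ± 19.2 to 202 ± 30.9 (SD, n = 4 each; log2 change -0.73 ± 0.15). GINS1, of the replication helicase complex, fell from 485 ± 35.6 to 310.4 ± 45.4 (-0.65 ± 0.14). On the 5 low-ribosomal arrays the values were -0.75 and -0.70, with no call on these fewer arrays (adjusted p = 0.0824 and 0.084). In the list for G2/M and mitosis 8 of 43 fell and 0 rose (adjusted over the list alone 11 and 0), with a median of -0.35 (adjusted p = 4.46e-08, and adjusted p = 0.27 with an estimated correlation). The mitotic kinase gene PLK1 fell from 299 ± 40.8 to 171 ± 23.7 (-0.79 ± 0.16) and the spindle checkpoint gene BUB1B from 565 ± 69.2 to 337 ± 52.5 (-0.74 ± 0.15). PLK1 was not called on the low-ribosomal arrays (-0.77, adjusted p = 0.0529). AURKA, another member that fell (adjusted p = 0.0446), lost its call in 7 of the 8 omissions of an array (adjusted p up to 0.127). On the low-ribosomal arrays AURKA was not called either (-0.87, adjusted p = 0.168). Of the ribosome biogenesis genes 8 of 27 fell and 0 rose (adjusted over the list alone 14 and 0), with a median of -0.42 (adjusted p = 2.22e-07, and adjusted p = 0.137 with an estimated correlation). BYSL, a factor of the small ribosomal subunit, fell from 319.7 ± 70.2 to 178 ± 24.5 (-0.81 ± 0.18) and kept its call in every omission of an array. NOP16, another member that fell, lost its call in 5 of the 8 omissions (adjusted p up to 0.111) and on the low-ribosomal arrays (-1.03, adjusted p = 0.138). Of the cytosolic ribosomal proteins 2 of 26 fell and 0 rose (adjusted over the list alone also 2 and 0), with a median of -0.16 (adjusted p = 0.00674, and adjusted p = 0.606 with an estimated correlation). This call was lost without EF-2-RNAi replicate 4 (adjusted p = 0.145) and with quantile normalization (adjusted p = 0.0906). The 2 were RPLP2 (276 ± 220.2 and 51.9 ± 10.2) and RPL38 (1106 ± 499 and 534 ± 23.3), whose probe sets can read near-identical copies. Their changes of -1.89 and -0.93 were -0.65 and -0.35 without the arrays of high ribosomal signal, with no call (adjusted p = 0.256 and 0.287). Both calls were also lost without luc-RNAi replicate 3 or 5, EF-2-RNAi replicate 4 or EF-4-RNAi replicate 8 (adjusted p up to 0.0973 and 0.119), with no filter (0.0542 and 0.0615) and without an intensity trend (0.0853 and 0.105). That of RPL38 was lost also without EF-2-RNAi replicate 2 (0.0714) and with the mean of its probe sets (0.0575). In the list of Polycomb and chromatin regulators 3 of 23 fell and 1 rose (adjusted over the list alone 5 and 1), with a median of -0.29 (adjusted p = 0.00317, and adjusted p = 0.18 with an estimated correlation). SMARCC1, a subunit of the SWI/SNF remodelling complex, fell from 508 ± 48.0 to 219.8 ± 80.6 (-1.26 ± 0.23) and the histone-binding gene RBBP4 from 458 ± 41.7 to 270.2 ± 52.1 (-0.77 ± 0.16). The DNA methyltransferases DNMT1 (-0.52 ± 0.13) and DNMT3B, the member that rose (0.77 ± 0.21), lost their calls in 5 and 6 of the 8 omissions of an array (adjusted p up to 0.0737 without luc-RNAi replicate 7 and 0.0868 without EF-2-RNAi replicate 4). DNMT1 was also not called with arrays scaled to the same median (0.0569) or without an intensity trend (0.0756), nor DNMT3B with no filter (0.0594) or on the low-ribosomal arrays (0.86, adjusted p = 0.109).

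Stress, immune and lysosomal genes were higher. In the unfolded protein response list 12 of 23 tested members rose and 0 fell (adjusted over the list alone 13 and 0), with a median log2 change of 0.78 (adjusted p = 2.77e-08, and adjusted p = 0.137 with an estimated correlation). HSPA5, the endoplasmic reticulum chaperone BiP, rose from 1041 ± 140.3 to 2495 ± 693 (SD, n = 4 each; log2 change 1.22 ± 0.19). XBP1, a transcription factor of this response, rose from 115 ± 9.63 to 310.3 ± 59.6 (1.38 ± 0.16). Of the immediate early and AP-1 genes 12 of 22 rose and 0 fell, with a median of 0.96. The call held with both correlations (adjusted p = 2.2e-06, and adjusted p = 0.0429 with an estimated correlation). Adjusted over the list alone, 12 rose and 1 fell. IER3 rose from 181 ± 34.7 to 1362 ± 573 (2.78 ± 0.29) and JUN, an AP-1 subunit, from 34.2 ± 9.23 to 131 ± 9.82 (1.85 ± 0.21). Of the inflammatory cytokines and NF-kB targets 7 of 22 rose and 0 fell (adjusted over the list alone 9 and 1), with a median of 0.63 (adjusted p = 1.68e-05, and adjusted p = 0.102 with an estimated correlation). Besides CXCL8 and PTX3 they included IL11, a cytokine, at 10.2 ± 3.72 and 95.1 ± 62.8 (2.57 ± 0.47). IL11 was not called with the mean of its probe sets (1.09, adjusted p = 0.0774). In the type I interferon response list 5 of 24 rose and 0 fell (adjusted over the list alone also 5 and 0), with a median of 0.32 (adjusted p = 0.00674, and adjusted p = 0.27 with an estimated correlation). The 5 were IFITM1 (1.30 ± 0.19), IFITM3 (1.29 ± 0.17), IRF9 (1.15 ± 0.22), OAS1 (1.33 ± 0.27) and, chosen after its value was seen, IFITM2 (0.72 ± 0.18). OAS1 was not called with the mean of its probe sets (adjusted p = 0.0519). The IFITM genes share a name stem, and whether their probe sets tell them apart was not examined. Of the HLA class I and antigen presentation genes 6 of 14 rose and 0 fell (adjusted over the list alone 9 and 0), with a median of 0.73 (adjusted p = 3.26e-05, and adjusted p = 0.228 with an estimated correlation). HLA-B stood at 245 ± 74.4 and 1601 ± 1022 (2.45 ± 0.43), but class I genes are near-identical and their probe sets cannot be assigned with certainty. The peptide transporter gene TAP1 rose from 33.6 ± 6.99 to 106 ± 33.1 (adjusted p = 0.00337). Of the lysosomal genes 9 of 20 rose and 0 fell (adjusted over the list alone 10 and 0), with a median of 0.51. This list too was called with both correlations (adjusted p = 1.23e-06, and adjusted p = 0.0429 with an estimated correlation). The cathepsin gene CTSL rose from 58.9 ± 12.2 to 258 ± 53.1 (2.06 ± 0.20) and NPC2, a cholesterol carrier of the lysosome, from 311 ± 20.4 to 792 ± 164 (1.32 ± 0.16).

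The other 16 lists were not called, although single members changed. Among neural genes 3 of 27 rose and 6 fell (median -0.14, adjusted p = 0.187). RET, a receptor tyrosine kinase, fell from 183 ± 93.7 to 30.4 ± 10.7 (SD, n = 4 each; -2.35 ± 0.34), and NEFL, a neurofilament gene, rose from 97.6 ± 63.1 to 385 ± 60.8 (2.16 ± 0.37). The other 2 that rose were the cell adhesion genes L1CAM (1.69 ± 0.45) and NCAM1 (1.47 ± 0.22), both chosen after their values were seen. Among osteogenic genes 4 of 9 rose and 1 fell (median -0.11, mean 0.89, tested direction up, adjusted p = 0.139). They were SPP1, COL1A1 (2.82 ± 0.61, not called with the mean of its probe sets, adjusted p = 0.0913), SPARC, a matrix glycoprotein (1.54 ± 0.20), MSX1, a homeobox gene (1.29 ± 0.30, chosen after its value was seen), and, falling, DLX5, another homeobox gene (-1.46 ± 0.30). Chondrogenic genes had 2 of 11 that rose (median 0.07, adjusted p = 0.511), the transcription factor gene SOX9 (1.04 ± 0.16) and the collagen gene COL9A3 (2.92 ± 0.40). Adipogenic genes had 3 of 11 (median 0.51, adjusted p = 0.162), CEBPD (1.29 ± 0.25), ANGPTL4 (1.58 ± 0.39) and KLF4 (1.69 ± 0.42). ANGPTL4 was not called without EF-2-RNAi replicate 2 or 4 or luc-RNAi replicate 5 (adjusted p up to 0.0605). KLF4 was not called without EF-2-RNAi replicate 4 or EF-4-RNAi replicate 6 (adjusted p up to 0.0586), nor on the low-ribosomal arrays (1.22, adjusted p = 0.16). Muscle genes had 0 of 6 (median 0.06, adjusted p = 0.739). Of the p53 target genes 3 of 18 rose, CDKN1A, GADD45B (1.13 ± 0.20) and PMAIP1 (0.84 ± 0.21), and 2 fell, FAS (-1.30 ± 0.32) and, chosen after its value was seen, CCNG1 (-0.72 ± 0.16; median 0.34, adjusted p = 0.139). Of the apoptosis regulators 2 of 22 rose, BIRC2 (1.86 ± 0.16) and TNFRSF1A (1.17 ± 0.14), and 1 fell, FAS (median 0.03, adjusted p = 0.623). PMAIP1 was not called without luc-RNAi replicate 3 or 5 or EF-2-RNAi replicate 2 or 4 (adjusted p up to 0.06) and FAS without luc-RNAi replicate 3 or 5 or EF-2-RNAi replicate 2 (up to 0.068). Without an intensity trend neither was called (0.072 and 0.0645), nor were GADD45B (0.90, adjusted p = 0.0514) and PMAIP1 (0.70, adjusted p = 0.0761) on the low-ribosomal arrays. In the glycolysis and hypoxia response list 6 of 25 rose and 1 fell (median -0.01, mean 0.36, tested direction up, adjusted p = 0.389). ADM, the adrenomedullin gene, rose from 44.2 ± 3.19 to 499 ± 331 (3.09 ± 0.41) and HK2, a hexokinase, fell (-0.92 ± 0.22, chosen after its value was seen). Of the Wnt pathway genes 2 of 18 rose, DKK1 and DKK3, and 3 fell, FZD4 (-0.79 ± 0.22), LRP6 (-0.70 ± 0.15) and, chosen after its value was seen, FZD1 (-0.66 ± 0.18; median 0.05, adjusted p = 0.696). Of the Notch pathway genes 1 of 10 rose, the ligand gene JAG1 (1.24 ± 0.20; median 0.02, adjusted p = 0.574). FZD4 lost its call in 6 omissions of an array, all but those of EF-4-RNAi replicates 6 and 8 (adjusted p up to 0.097). On the low-ribosomal arrays FZD4 and LRP6 had values of -0.89 and -0.71, with no call on these fewer arrays (adjusted p = 0.107 and 0.0967). Of the cholesterol biosynthesis genes 1 of 16 rose, INSIG1 (76.4 ± 11.3 and 249 ± 141; median 0.09, adjusted p = 0.596). Of the histones 1 of 9 fell, H2AZ1 (-0.43 ± 0.11; median 0.39, mean 0.16, adjusted p = 0.669). The call of INSIG1 was lost on the low-ribosomal arrays (1.55, adjusted p = 0.0675), and that of H2AZ1 there (-0.44, adjusted p = 0.134), without an intensity trend (0.0929) and without luc-RNAi replicate 3 or 7 or EF-2-RNAi replicate 4 (up to 0.0633). Among markers of other cell types, epithelial markers had 0 of 9 called (median -0.49, adjusted p = 0.139), and haematopoietic markers had 1 of 11 that fell, CD79A (-1.95 ± 0.45; median -0.20, adjusted p = 0.26). Endothelial markers had 1 of 9 that rose, ENG (1.71 ± 0.34), and 1 that fell, EGFL7 (-1.28 ± 0.28; median 0.19, adjusted p = 0.669). CD79A and EGFL7 had values of -1.97 and -1.31 on the low-ribosomal arrays, with no call on these fewer arrays (adjusted p = 0.0974 and 0.0574). Of 22 commonly used reference genes 3 rose, PPIB (1.02 ± 0.12), REEP5 (0.84 ± 0.20) and CHMP2A (0.66 ± 0.16), and 1 fell, SNRPD3 (-0.49 ± 0.13), around a median of -0.06 (mean 0.04, tested direction up, adjusted p = 0.974). Of these 4, REEP5 was not called without luc-RNAi replicate 5 (adjusted p = 0.0524), nor CHMP2A without EF-2-RNAi replicate 2, luc-RNAi replicate 3 or 5 or EF-4-RNAi replicate 8 (up to 0.0604). SNRPD3 was not called without luc-RNAi replicate 1, 3 or 7 or EF-2-RNAi replicate 2 or 4 (up to 0.0873). On the low-ribosomal arrays the values of these 3 were 0.84, 0.68 and -0.62, with no call on these fewer arrays (adjusted p = 0.0579, 0.111 and 0.0726). In all, 17 of 33 lists were called, 11 up and 6 down, and 3 of them also with an estimated correlation. Some lists share members, so these are not separate results. For example, IGFBP3, IGFBP5 and IGFBP7 are in both the EWS/FLI-repressed and the insulin-like growth factor lists, and CXCL8 is in both the EWS/FLI-repressed and the inflammatory lists. NPY1R is in both the EWS/FLI-activated and the neural lists, and KLF4 in both the adipogenic and the immediate early lists.

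**Figure D2:**
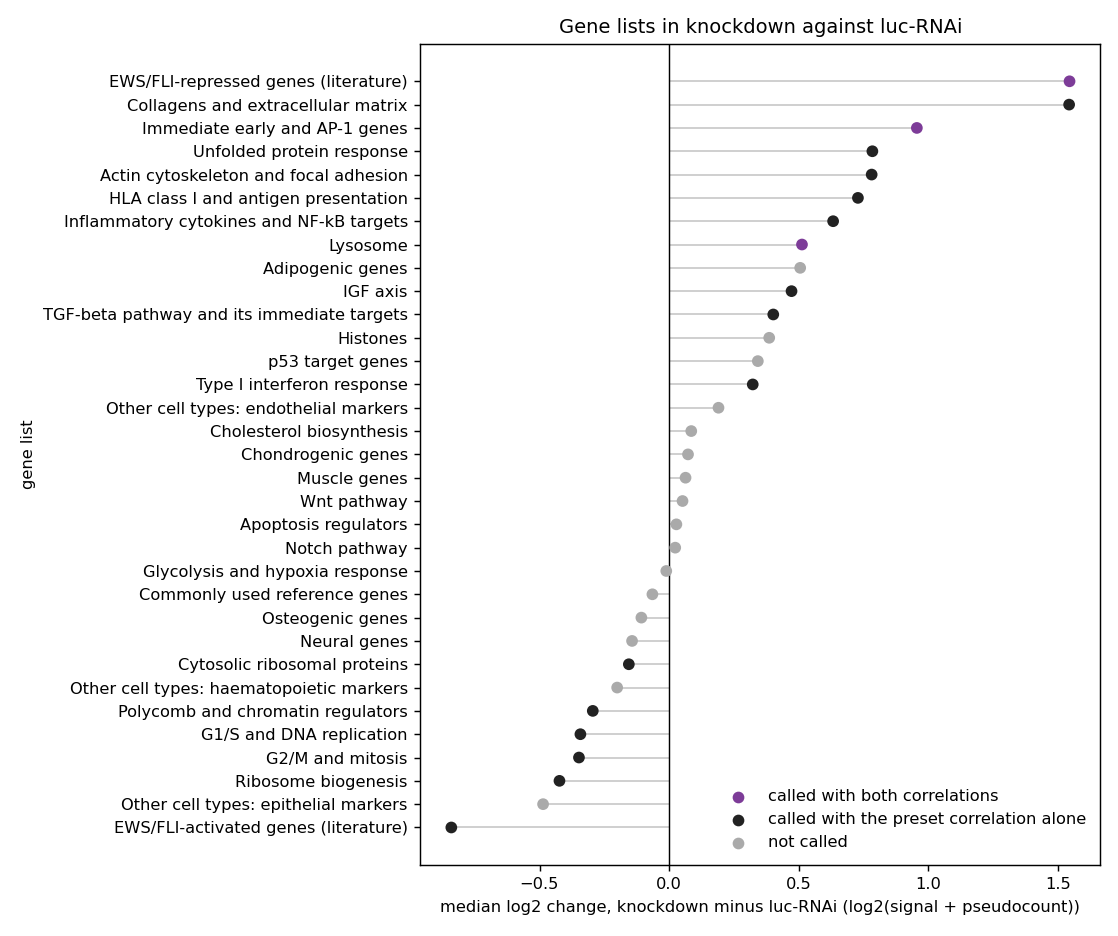
Median log2 change, knockdown minus luc-RNAi, of the 33 gene lists over 8 arrays, on the log2(intensity + 4.05) scale. Purple points mark the 3 lists called with both correlations, black points those called with the preset correlation alone, and grey points the 16 lists not called. Medians run from -0.84 for EWS/FLI-activated genes to 1.54 for EWS/FLI-repressed genes.

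With each construct against luc-RNAi, CXCL8 rose to 761 ± 142 with EF-2-RNAi and 460.1 ± 274 with EF-4-RNAi (SD, n = 2 each), log2 changes of 6.29 ± 0.37 and 5.44 ± 0.37 (SE, adjusted p = 4.61e-08 and 1.79e-06). IGFBP5 rose to 1426 ± 419 and 1405 ± 1029.6 (5.94 ± 0.38 and 5.72 ± 0.38, adjusted p = 1.13e-07 and 1.79e-06). DKK1 rose to 352 ± 22.5 and 463 ± 40.1 (2.84 ± 0.20 and 3.23 ± 0.20, adjusted p = 2.99e-07 and 1.71e-06). PPP1R1A fell to 1.78 ± 0.0761 with EF-2-RNAi and 3.80 ± 1.12 with EF-4-RNAi (-5.20 ± 0.38 and -4.77 ± 0.38, adjusted p = 4.56e-07 and 4.47e-06). GSTM4 fell to 29.8 ± 21.8 and 34.3 ± 8.27 (-2.95 ± 0.33 and -2.61 ± 0.33, adjusted p = 2.02e-05 and 0.000198). EF-2-RNAi called 2852 probe sets (1641 higher, 1211 lower) and 1815 genes. With quantile normalization 49.6% of its called probe sets were higher, in place of 57.5%. EF-4-RNAi called 1438 probe sets (909 higher, 529 lower) and 955 genes. Without EF-2-RNAi replicate 2 or 4, EF-2-RNAi called 1637 and 1738 probe sets. Without EF-4-RNAi replicate 6 or 8, EF-4-RNAi called 802 and 490, where the array left in its group is assumed to vary like the others.

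Both constructs called 955 probe sets in the same direction, 672 higher and 283 lower, and 17 in opposite directions. Independent lists of these sizes would share 96.6 higher and 41.5 lower calls. Both comparisons used the same luc-RNAi arrays. In 100 draws with all 8 arrays simulated without any effect, the constructs shared 0 calls by limma on average. With no effect few calls can arise, so these draws cannot show how far the same luc-RNAi arrays raise the number of shared calls. The log2 changes of the constructs correlated with r = 0.645 across probe sets, which are not independent replicates, against 0.334 in the simulation, and their signs were the same for 69.4% against 60.8%. Their covariance was 0.330, against 0.0456 simulated, a difference of 0.284. With 2 luc-RNAi arrays for each construct, the 6 splits gave 486 to 638 shared calls and r between 0.478 and 0.531. Without EF-4-RNAi replicate 8 there were 329 shared calls (r = 0.510).

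**Figure D3:**
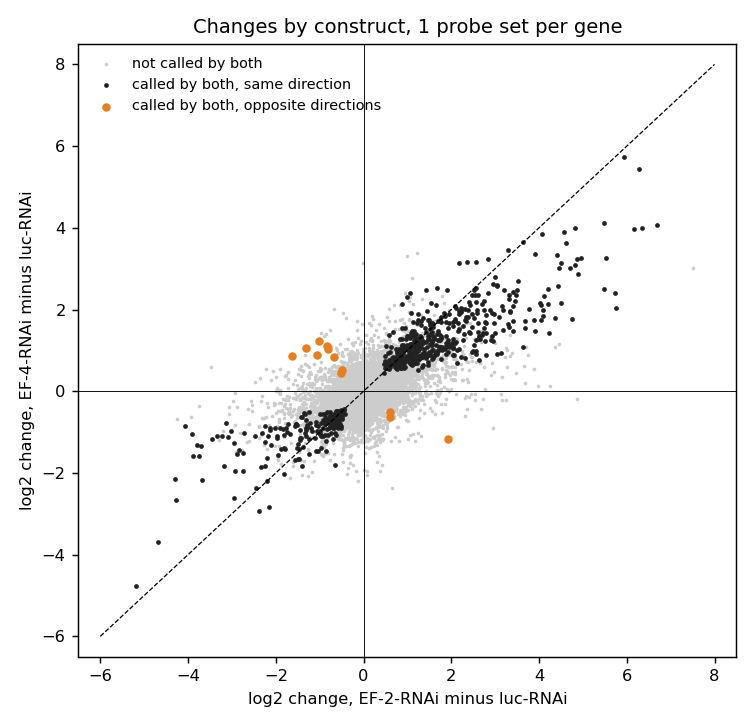
Log2 change against luc-RNAi with EF-2-RNAi (horizontal axis) and EF-4-RNAi (vertical axis) for 9239 genes, 1 probe set per gene, with a dashed line of equal change. Black points are the 642 genes called by both in the same direction, and orange points the 12 called by both in opposite directions.

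EF-4-RNAi arrays kept several genes nearer to the luc-RNAi level than EF-2-RNAi arrays did. NELL2, which encodes a secreted neural glycoprotein, stood at 2456 ± 214 in luc-RNAi (SD, n = 4), 158 ± 24.6 in EF-2-RNAi and 1654 ± 670.3 in EF-4-RNAi (SD, n = 2 each). The log2 difference of EF-4-RNAi minus EF-2-RNAi was 3.30 ± 0.23 (SE, adjusted p = 4.55e-06). GRIK2, a glutamate receptor subunit, stood at 6.23 ± 0.115 and 119 ± 10.3 (3.58 ± 0.26, adjusted p = 7.58e-06). TSPAN8, a tetraspanin, had the largest positive difference, 17.8 ± 8.23 against 450.4 ± 405 (4.07 ± 0.52, adjusted p = 0.000437). DKK2, a Wnt modulator, stood at 12.8 ± 10.7 and 169 ± 97.5 (3.39 ± 0.44, adjusted p = 0.000473). For EF-4-RNAi against luc-RNAi, TSPAN8 had a log2 value of 0.60, which became -0.47 without EF-4-RNAi replicate 6 and -0.52 on the low-ribosomal arrays. DKK2 had one of -0.36, which became 0.25 without EF-4-RNAi replicate 8, with no call. Of the genes lower in EF-4-RNAi, LSP1, a leukocyte actin-binding protein, stood at 252 ± 91.8 in EF-2-RNAi and 3.43 ± 1.37 in EF-4-RNAi (-5.06 ± 0.67, adjusted p = 0.000591). KCNMA1, a potassium channel gene, stood at 299 ± 45.1 and 14.9 ± 10.9 (-4.12 ± 0.58, adjusted p = 0.000893). IGFBP7 stood at 1411 ± 121 and 191 ± 262 (-4.50 ± 1.04), SLC14A1, a urea transporter gene, at 86.4 ± 49.6 and 1.83 ± 1.80 (-3.86 ± 0.86), and WNT5B, a Wnt ligand gene, at 113 ± 4.16 and 4.83 ± 4.77 (-3.83 ± 0.84). Adjusted p for these 3 lay between 0.0166 and 0.0211. The call of LSP1 was lost without EF-2-RNAi replicate 4 (adjusted p = 0.0502), and that of IGFBP7 without EF-2-RNAi replicate 2 or 4 (up to 0.139). Those of SLC14A1 and WNT5B were lost without EF-2-RNAi replicate 2 or 4 or EF-4-RNAi replicate 6 (up to 0.24 and 0.179). IGFBP7 was also not called with no filter (0.0609) or without an intensity trend (0.13), SLC14A1 on the low-ribosomal arrays (-3.54, adjusted p = 0.0585), and WNT5B with the smaller pseudocount (0.087) or the stricter filter (0.0717). With high and low ribosomal signal as a block, IGFBP7, SLC14A1 and WNT5B were not called either (0.0542, 0.0548 and 0.0536).

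Between the constructs 828 probe sets were called, 361 higher and 467 lower in EF-4-RNAi, and 543 genes. The share of higher calls, 43.6%, became the larger one with quantile normalization (51.5%), with arrays scaled to the same median (52.6%), and without EF-2-RNAi replicate 2 (53.2%) or 4 (59.4%). Without EF-2-RNAi replicate 2, EF-2-RNAi replicate 4 or EF-4-RNAi replicate 6 these were 333, 392 and 247 probe sets. There were 233 higher calls both without EF-2-RNAi replicate 4 and without EF-4-RNAi replicate 8. EF-2-RNAi had only the title numbers 2 and 4, and EF-4-RNAi only 6 and 8. The constructs therefore cannot be told apart from an effect that goes with these numbers. On the third principal component (10.7% of the variance) luc-RNAi replicates 1 and 3 lay at 37.1 and 13.5, and 5 and 7 at -24.2 and -21.6. Consecutive title numbers as a block gave 298 called probe sets, 152 higher and 146 lower. With the preset correlation 12 of the 33 lists were called, 6 higher and 6 lower in EF-4-RNAi, and none was called with an estimated correlation. Collagens and matrix genes were lower in EF-4-RNAi, with 15 of 41 members lower and 3 higher (median log2 difference -0.86, adjusted p = 4.8e-08, and adjusted p = 0.314 with an estimated correlation). COL1A1, a chain of type I collagen, stood at 4024 ± 369 in EF-2-RNAi and 599 ± 256 in EF-4-RNAi (SD, n = 2 each; -2.80 ± 0.34, adjusted p = 0.000282). EWS/FLI-activated genes were higher, with 12 of 38 higher and 1 lower (median 0.43, adjusted p = 1.74e-07, and adjusted p = 0.107 with an estimated correlation). EWS/FLI-repressed genes were lower, with 9 of 28 lower and 1 higher (median -0.39, adjusted p = 0.00211, and adjusted p = 0.425 with an estimated correlation).

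Other lists also differed between the constructs. Of the neural genes 5 of 27 were higher and 0 lower (median 0.54, adjusted p = 3.17e-05, and adjusted p = 0.107 with an estimated correlation). Among them were NPY1R (2.14 ± 0.29), which is also in the EWS/FLI-activated list, and NKX2-2 (0.98 ± 0.26), and GAP43, NEFM and ENO2, chosen after their values were seen. Of the cholesterol biosynthesis genes 4 of 16 were higher and 0 lower (median 0.57, adjusted p = 5.48e-07, and adjusted p = 0.107 with an estimated correlation). These were INSIG1 (1.25 ± 0.26) and, chosen after their values were seen, MSMO1, DHCR7 and FDPS. NKX2-2 and INSIG1 lost these calls without EF-2-RNAi replicate 2 or 4, and also without EF-4-RNAi replicate 6 or luc-RNAi replicate 3 or 7 (NKX2-2, adjusted p up to 0.373) or EF-4-RNAi replicate 8 (INSIG1, up to 0.119). Of the ribosomal proteins 3 of 26 were higher and 0 lower (median 0.38, adjusted p = 1.74e-07, and adjusted p = 0.285 with an estimated correlation), namely RPS19 (0.74 ± 0.15), RPL18 (0.54 ± 0.15) and RPS12 (0.51 ± 0.13). Of the ribosome biogenesis genes 1 of 27 was higher, NOLC1 (1.38 ± 0.25; median 0.23, adjusted p = 0.00122, and adjusted p = 0.314 with an estimated correlation). All 4 were chosen after their values were seen. Of the genes of G2/M and mitosis 5 of 43 were lower and 0 higher (median -0.43, adjusted p = 1.75e-07, and adjusted p = 0.285 with an estimated correlation). The 5 were CDC20 (-0.87 ± 0.17), BIRC5 (-0.84 ± 0.23), RACGAP1 (-0.76 ± 0.20), KIF20A (-0.75 ± 0.20) and CCNB1 (-0.67 ± 0.18), chosen after their values were seen. Of the actin and focal adhesion genes 10 of 38 were lower and 1 higher (median -0.47, adjusted p = 0.00021, and adjusted p = 0.341 with an estimated correlation). Of the HLA class I and antigen presentation genes 4 of 14 were lower and 0 higher (median -0.53, adjusted p = 0.00594, and adjusted p = 0.486 with an estimated correlation). The 4 were HLA-B (-1.74 ± 0.34), HLA-C (-1.39 ± 0.23), PSMB9 (-1.55 ± 0.32) and, chosen after its value was seen, HLA-G (-0.90 ± 0.21). Without EF-2-RNAi replicate 4 or EF-4-RNAi replicate 6, HLA-B and PSMB9 were not called, nor PSMB9 without EF-2-RNAi replicate 2 (adjusted p up to 0.115 and 0.142). Of the glycolysis and hypoxia genes 4 of 25 were lower, ADM (-1.88 ± 0.22), NDRG1 (-1.40 ± 0.32; not called without EF-2-RNAi replicate 4 or EF-4-RNAi replicate 6, adjusted p up to 0.23) and, chosen after their values were seen, VEGFA (-1.33 ± 0.30) and LDHA (-0.71 ± 0.14). In that list 1 was higher, PFKM (0.75 ± 0.17, likewise; median -0.38, adjusted p = 0.0104, and adjusted p = 0.154 with an estimated correlation). With the preset correlation the call of ribosome biogenesis was lost without EF-4-RNAi replicate 6 (adjusted p = 0.0809), and that of HLA class I without that array (adjusted p = 0.198) or EF-2-RNAi replicate 4 (adjusted p = 0.136). Both calls were lost on the low-ribosomal arrays (medians 0.17 and -0.13, adjusted p = 0.0786 and 0.165), and that of glycolysis and hypoxia without EF-4-RNAi replicate 8 (adjusted p = 0.131). Of the unfolded protein response genes 5 of 23 were higher and 0 lower (median 0.55, adjusted p = 9.19e-07, and adjusted p = 0.118 with an estimated correlation). They included TRIB3 (1.68 ± 0.21), ATF3 (1.25 ± 0.26) and PDIA4 (0.70 ± 0.19), all 3 chosen after their values were seen. ATF3 was not called without EF-2-RNAi replicate 4 or EF-4-RNAi replicate 6 (adjusted p up to 0.127), nor on the low-ribosomal arrays (1.16, adjusted p = 0.172). Of the genes named above for these lists, NKX2-2 (0.69, adjusted p = 0.483), HLA-B (-1.15, adjusted p = 0.0667), PSMB9 (-1.28, adjusted p = 0.124) and NDRG1 (-1.09, adjusted p = 0.141) were not called there either. The other 2 were HERPUD1 and DNAJB9. HERPUD1, of protein degradation at the endoplasmic reticulum, stood at 149 ± 17.9 in luc-RNAi (n = 4), 316 ± 43.0 in EF-2-RNAi and 806 ± 36.4 in EF-4-RNAi (1.35 ± 0.20, adjusted p = 0.00129). The co-chaperone gene DNAJB9 stood at 113 ± 15.8, 229.6 ± 45.6 and 582 ± 136 (1.32 ± 0.24, adjusted p = 0.00503). DNAJB9 was not called without EF-2-RNAi replicate 2 or EF-4-RNAi replicate 8 (adjusted p = 0.068 and 0.0512).

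**Figure D4:**
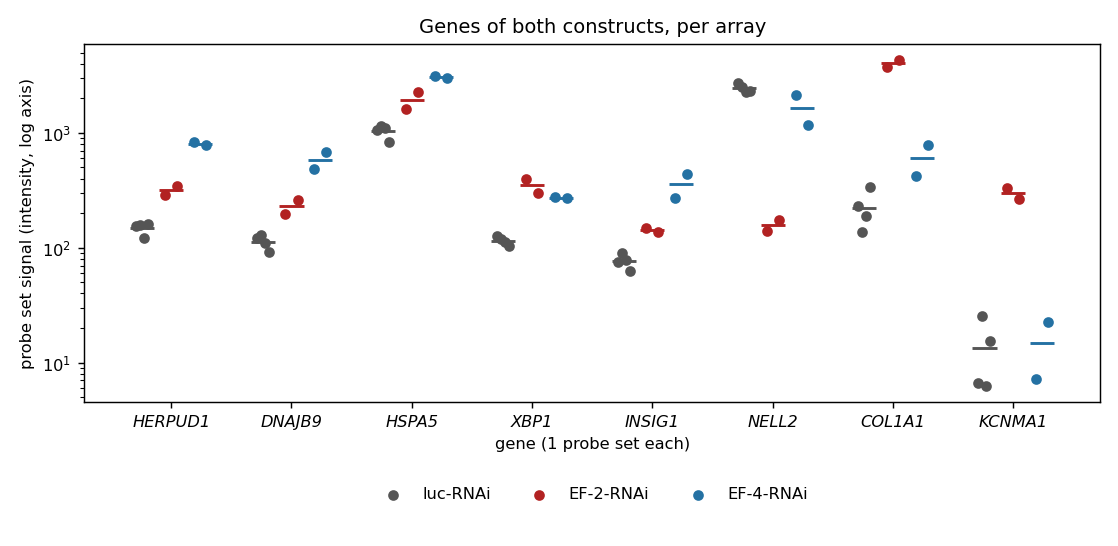
Signal (intensity, log axis) of 8 genes on the 8 arrays, with points for arrays and lines for group means. HERPUD1 and DNAJB9 were highest in EF-4-RNAi (means 806 and 582), whereas COL1A1 was highest in EF-2-RNAi (mean 4024) and NELL2 lowest there (mean 158).

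Among the 654 genes that both constructs called, 642 changed the same way and 12 in opposite directions. In 9 of the 12, EF-2-RNAi was lower and EF-4-RNAi higher than luc-RNAi. These included HMGA2, an architectural chromatin protein (luc-RNAi 618 ± 65.0, SD, n = 4, EF-2-RNAi 385 ± 33.7 and EF-4-RNAi 1106 ± 171, SD, n = 2 each). Its log2 changes were -0.67 ± 0.15 and 0.83 ± 0.15 (adjusted p = 0.00644 and 0.00334). SCG2, which encodes secretogranin II, changed by -1.02 ± 0.21 and 1.23 ± 0.21, and ID4, an inhibitor of basic helix-loop-helix factors, by -1.30 ± 0.25 and 1.06 ± 0.25. BACE1, the beta-secretase, went the other way, with changes of 1.92 ± 0.31 and -1.18 ± 0.31. In EF-2-RNAi the calls were lost without EF-2-RNAi replicate 2 for HMGA2 (adjusted p = 0.0904) and without EF-2-RNAi replicate 4 for SCG2 (0.086). In EF-4-RNAi they were lost without EF-4-RNAi replicate 6 for HMGA2 (0.0663) and without EF-4-RNAi replicate 8 for ID4 (0.254). That of BACE1 was lost without EF-4-RNAi replicate 6 or 8, EF-2-RNAi replicate 2 or 4 or luc-RNAi replicate 3 (up to 0.129). On the low-ribosomal arrays the calls of HMGA2 (-0.56 and 0.79, adjusted p = 0.0593 and 0.0713) and the EF-4-RNAi calls of SCG2 (1.07, adjusted p = 0.13) and BACE1 (-1.11, adjusted p = 0.257) were lost. Lost with the mean of its probe sets was that of ID4 (0.284). All 12 were chosen after their values were seen, and the others were ADRA1D, ATP6V1G1, COL21A1, PLTP, SRP54, TGIF1, TMEM100 and UBE2E3. Each of the 12 lost a call with at least 1 construct when 1 array was left out.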

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

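The tests on EF-2-RNAi against EF-4-RNAi arrays and on the unfolded protein response below were chosen after the results were seen, as were the fits with ribosomal signal and the GAPDH ratio. The splits of the arrays were planned.

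In 5 of 126 genes, 1 luc-RNAi array lay far from the other 3 by Dixon's test on the log2 scale, against about 6.3 of 126 by chance (1 in 20). ADM stood at 39.5 on luc-RNAi replicate 5 (others 45.1 to 46.3), CTSB at 395 on luc-RNAi replicate 1 (198 to 212), FOSL2 at 6.08 on luc-RNAi replicate 7 (19.0 to 20.9), HERPUD1 at 122 on luc-RNAi replicate 5 (154 to 160.3) and MEF2C at 5.42 on luc-RNAi replicate 5 (28.7 to 32.4).

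In 41 of the 126 genes the log2 change against luc-RNAi differed between the constructs by the test of the difference itself, EF-4-RNAi minus EF-2-RNAi (adjusted p from 4.55e-06 to 0.0449). In 38 of the 41 the change was smaller or of the other sign in EF-4-RNAi, which includes the 10 genes that were named for their difference between the constructs. The calls of 16 held in every omission of 1 array: ADM -1.88, ARHGAP19 3.23, CAV1 0.77, COL1A1 -2.80, DKK2 3.39, ENG -1.49, GRIK2 3.58, HERPUD1 1.35, HLA-C -1.39, IGFBP3 -2.63, KCNMA1 -4.12, MYOM2 2.30, NELL2 3.30, NPY1R 2.14, SLC24A3 2.47 and TSPAN8 4.07. Those of the other 25 were lost in at least 1 omission. With the highest adjusted p in brackets and each array left out alone, CD9 -2.20 (0.245), DKK3 -2.37 (0.265), LOXL2 -1.61 (0.301), PSMB9 -1.55 (0.142), SLC14A1 -3.86 (0.24) and WNT5B -3.83 (0.179) were not called without EF-2-RNAi replicate 2 or 4 or EF-4-RNAi replicate 6. COL6A2 -2.26 (0.0762), FAS 1.25 (0.221), HLA-B -1.74 (0.115) and NDRG1 -1.40 (0.23) were not called without EF-2-RNAi replicate 4 or EF-4-RNAi replicate 6. FZD4 0.88 (0.0669), IGFBP6 -1.18 (0.328), ITGA3 -2.26 (0.316) and TGFBR2 -0.97 (0.225) were not called without EF-2-RNAi replicate 2 or 4 or EF-4-RNAi replicate 6 or 8. LOX -1.69 (0.1), MYC 1.37 (0.195) and SMARCC1 0.92 (0.115) were not called without EF-2-RNAi replicate 2 or EF-4-RNAi replicate 6. DLX5 1.14 (0.25) was not called without luc-RNAi replicate 3, EF-2-RNAi replicate 2 or EF-4-RNAi replicate 6 or 8. DNAJB9 1.32 (0.068) was not called without EF-2-RNAi replicate 2 or EF-4-RNAi replicate 8. IER3 -1.06 (0.382) was not called without luc-RNAi replicate 3, EF-2-RNAi replicate 2 or 4 or EF-4-RNAi replicate 6. IGFBP7 -4.50 (0.139) was not called without EF-2-RNAi replicate 2 or 4. INSIG1 1.25 (0.119) was not called without EF-2-RNAi replicate 2 or 4 or EF-4-RNAi replicate 8. LSP1 -5.06 (0.0502) was not called without EF-2-RNAi replicate 4. NKX2-2 0.98 (0.373) was not called without luc-RNAi replicate 3 or 7, EF-2-RNAi replicate 2 or 4 or EF-4-RNAi replicate 6. TENM1 2.17 (0.0595) was not called without EF-4-RNAi replicate 6.

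The number of genes called in knockdown against luc-RNAi is the first pattern weighed. No other of the 35 splits of the 8 arrays into 4 and 4 called as many probe sets as the real one, 1865 against at most 0. For gene lists the real split also ranked first, with 17 against at most 16, a margin of 1. First place in 35 is a share of 2.86%, the smallest these splits can give. It argues against chance assignment of the arrays for both counts but cannot exclude it. Every other split mixes luc-RNAi and knockdown arrays within an arm, so a knockdown effect would raise its spread and lower its count of probe sets. The 16 splits with 3 luc-RNAi arrays in 1 arm, which keep part of the knockdown effect, called 10 to 16 lists, whereas the 12 with 2 luc-RNAi arrays and 1 array of each construct in both arms called 0 to 2. For single lists, 13 of the 17 called had their largest median in the real split. These 17 were picked by their call in that split, and the uncalled adipogenic, histone and epithelial lists also had their largest median there. For 4 called lists medians as large came in several splits, in 9 of 35 for cytosolic ribosomal proteins, 3 for type I interferon genes and 2 each for G2/M and inflammatory genes. With log2 ribosomal signal as a covariate 1487 probe sets were called and with the GAPDH 3' to 5' ratio 1559, which argues against either as the whole source of the calls, and a difference between cultures that goes with the constructs stays open and was not tested.

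The second pattern is that EF-2-RNAi arrays differed more from luc-RNAi than EF-4-RNAi arrays did. Over the 1190 genes called in knockdown, the mean change in the called direction was 1.46 and 1.48 log2 units on EF-2-RNAi replicates 2 and 4, against 0.94 and 1.18 on EF-4-RNAi replicates 6 and 8, a ratio of 0.722. For EF-4-RNAi cultures as a mixture of EF-2-like and luc-like cells, 90 genes were called on the same side of both luc-RNAi and EF-2-RNAi. The false calls allowed in both comparisons together were 74.9, an expected number and not an upper limit. Both comparisons used the same EF-4-RNAi arrays, and the count was not repeated without either of them. Only 13 of the 90 are among the 1190, whose fit counted the difference between the constructs as spread. This count therefore cannot decide the question, and a mixture stays open. Replicate 6, an array of high ribosomal signal, as the whole source is argued against by replicate 8, which lay nearer to luc-RNAi than the lower EF-2-RNAi array (mean SD of log2 differences 0.788 against 0.955, a gap of 0.167, with an SD of 0.0196 between arrays of a group). Less reduction of FLI1 transcript by EF-4-RNAi may play a part and cannot be told apart from other differences between the constructs, since the mean difference over the 3 FLI1 probe sets was 0.42 log2 units with a 95% interval from -0.13 to 0.97.

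The third pattern is that unfolded protein response genes were higher in EF-4-RNAi than in EF-2-RNAi (median 0.55 over 23 genes). Replicate 6 as its source is argued against by the median without that array, 0.62, with 20 of 23 genes higher on replicate 8 than the EF-2-RNAi mean. Scaling of the arrays is argued against by a median that lay 0.60 above that of all genes after quantile normalization. The median against the luc-RNAi mean was 0.46 and 0.51 on the EF-2-RNAi arrays and 1.00 and 1.12 on the EF-4-RNAi arrays. A difference between the constructs or their cultures stays open and was not tested, and the list's call was lost with an estimated correlation (adjusted p = 0.118).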

How the results depend on the processing

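Alternatives that use ribosomal signal or the GAPDH ratio, and the omissions of single arrays for the overlap, were chosen after the data had been seen. The others were planned. Knockdown against luc-RNAi called 1865 probe sets (1166 higher, 699 lower) and 1190 genes. EF-2-RNAi against luc-RNAi called 2852 (1641, 1211), EF-4-RNAi against luc-RNAi 1438 (909, 529), and EF-4-RNAi against EF-2-RNAi 828 (361, 467). Counts moved by over 1.5 times as follows. The cause was not tested, and where arrays were left out fewer arrays were used. Without an intensity trend, knockdown called 1233 (388 lower, 789 genes) and EF-2-RNAi 789 lower. EF-4-RNAi called 699 (498 higher, 201 lower), and EF-4-RNAi against EF-2-RNAi 347 (165 higher, 182 lower). With only the arrays of low ribosomal signal the counts were 1034 (752 higher, 282 lower, 667 genes), 758 lower, 607 (464 higher, 143 lower) and 250 (101 higher, 149 lower). The constructs shared 471 calls there, and fewer arrays were used. EF-4-RNAi was replicate 8 alone there, which is assumed to vary like the others. With the 3-group fit knockdown called 1151 lower. With the GAPDH ratio as a covariate knockdown called 463 lower and EF-4-RNAi 335 lower. With arrays scaled to the same median EF-4-RNAi called 297 lower and EF-4-RNAi against EF-2-RNAi 278 lower. With high and low ribosomal signal as a block the latter called 303 lower. The share of higher calls in knockdown was 62.5%, and ran from 57.6% with quantile normalization to 72.7% on the low-ribosomal arrays. With quantile normalization the share turned for EF-2-RNAi (49.6% in place of 57.5%). For EF-4-RNAi against EF-2-RNAi (43.6%) it turned with quantile normalization (51.5%), with the same median (52.6%), and without EF-2-RNAi replicate 2 (53.2%) or 4 (59.4%), and also in the block fit given last. With an estimated correlation 3 lists were called in place of 17 for knockdown and 0 in place of 12 between the constructs. With luc-RNAi arrays split between the constructs, shared calls were 609 (arrays 1 and 3 for EF-2-RNAi), 486 (1 and 5), 621 (5 and 7), 526 (3 and 7) and 576 (3 and 5) in place of 955. With the same splits r was 0.478 (1 and 3), 0.490 (1 and 7) and 0.505 (5 and 7) in place of 0.645.

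Leaving out each array in turn, knockdown called 1144 to 2249 probe sets (819 to 1415 higher, 325 to 834 lower) and 756 to 1432 genes. EF-2-RNAi called 1637 to 2786 (965 to 1620, 654 to 1185) and EF-4-RNAi 490.0 to 1368 (297 to 874, 193 to 539). EF-4-RNAi against EF-2-RNAi called 247 to 914 (117 to 393, 130 to 521), where a lone array is assumed to vary like the others. Lists called ranged from 16 to 17 and from 10 to 13, shared calls from 329 to 903 and r from 0.510 to 0.660. The lowest counts came without luc-RNAi replicate 3 (knockdown, 1144), EF-2-RNAi replicate 2 (EF-2-RNAi, 1637), EF-4-RNAi replicate 8 (EF-4-RNAi, 490.0, and shared calls, 329) and EF-4-RNAi replicate 6 (EF-4-RNAi against EF-2-RNAi, 247). Of 112 named genes called in knockdown, 84 were called in every omission and 28 were not. Of the 112, 24 were not called without an intensity trend, 32 on the low-ribosomal arrays, 12 with the GAPDH ratio and 11 with the ribosomal covariate. Calls were also lost for 11 with the mean of probe sets, 10 with no filter, 8 with the ribosomal block, 6 with the same median, 2 with quantile normalization, 2 with the smaller pseudocount and 0 with the larger one or 3 groups. The stricter filter let 110 of the 112 pass, and 1 of these was not called.

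Signs turned for some values that were not called on either side. The cause was not tested. In knockdown CCND1 (0.10) was -0.034 with the mean of probe sets and -0.067 on the low-ribosomal arrays. For EF-4-RNAi against luc-RNAi, DKK2 (-0.36) lay between -0.97 and 0.25 over the omissions, positive only without EF-4-RNAi replicate 8. KCNMA1 (0.12) lay between -0.51 and 0.74, negative without luc-RNAi replicate 1 (-0.073), luc-RNAi replicate 5 (-0.088) and EF-4-RNAi replicate 8 (-0.51). LSP1 (-0.18) lay between -0.37 and 0.0041, positive without EF-4-RNAi replicate 6, and was 0.058 with the GAPDH covariate. TSPAN8 (0.60) lay between -0.47 and 1.67, negative without EF-4-RNAi replicate 6, and was -0.52 on the low-ribosomal arrays. WNT5B (0.14) lay between -0.44 and 0.71, negative without EF-4-RNAi replicate 8, and was -0.075 with consecutive title numbers as a block. MYC (0.036) lay between -0.41 and 0.48, negative without luc-RNAi replicate 5 (-0.10) and EF-4-RNAi replicate 6 (-0.41), and was -0.63 on the low-ribosomal arrays. For EF-2-RNAi against luc-RNAi, FOXO1 (0.20) lay between -0.0049 (without luc-RNAi replicate 7) and 0.37, and was -0.21 with the mean of probe sets and -0.20 with consecutive title numbers as a block.

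Camera's direction, which need not have the sign of a list's median or mean log2 value, turned for some uncalled lists. In knockdown these were muscle genes (median -0.043 without luc-RNAi replicate 1, omissions up to 0.17) and cholesterol biosynthesis (-0.066 without EF-4-RNAi replicate 6, omissions up to 0.18, and -0.025 on the low-ribosomal arrays). Apoptosis regulators (0.017) turned with the GAPDH covariate. Reference genes turned with the same median (-0.10), without EF-4-RNAi replicate 6 (-0.092) or luc-RNAi replicate 7 (-0.079), on the low-ribosomal arrays (-0.12) and with the GAPDH covariate (-0.13), and reached -0.026 over the omissions. For EF-4-RNAi against EF-2-RNAi osteogenic genes turned with no filter (0.23) and without EF-2-RNAi replicate 4 (0.26) or EF-4-RNAi replicate 6 (0.058), with omissions down to -0.60. Muscle genes turned with the mean of probe sets (-0.20) and without EF-2-RNAi replicate 4 (-0.13) or EF-4-RNAi replicate 8 (-0.19), with omissions up to 0.23. The p53 targets turned with the mean of probe sets (-0.081), with no filter (0.00085) and without EF-2-RNAi replicate 4 (-0.079) or EF-4-RNAi replicate 8 (-0.089), with omissions up to 0.24. Without EF-4-RNAi replicate 8 inflammatory genes (-0.31, omissions up to 0.37) and lysosomal genes (0.020, omissions up to 0.14) turned too.

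The groups share no replicate number, and a paired fit was run only with consecutive title numbers as a block. In it EF-4-RNAi called 325 lower and EF-4-RNAi against EF-2-RNAi 298 (152 higher, 146 lower, 51.0% higher), but residuals of consecutive arrays correlated by only 0.04, -0.03, -0.03 and 0.15, so the numbers were not taken as pairs. The filter on low values limits the tests to 15445 of 22215 probe sets, and those with fewer than 2 arrays above 29.0 were not tested.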

Other observations

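The tests of gene families in this part were chosen after the data had been seen. Among 150 families of at least 8 genes that share a name stem, 11 were called by camera in knockdown against luc-RNAi with the preset correlation, and none with an estimated correlation (smallest adjusted p = 0.504). Genes of the SEC stem, most of them parts of protein export from the endoplasmic reticulum, were higher, with 8 of 22 called higher and 0 lower (median log2 0.41, adjusted p = 7.61e-05). Among them were the coat protein genes SEC24D (1.57 ± 0.22, SE), SEC23A (1.27 ± 0.19) and SEC31A (0.82 ± 0.15), n = 4 arrays each. The annexin stem ANXA had 4 of 10 higher and 0 lower (median 0.45, adjusted p = 0.00795), ANXA4 (2.14 ± 0.29), ANXA6 (1.09 ± 0.20), ANXA5 (0.74 ± 0.13) and ANXA11 (0.65 ± 0.19). Its 10 members include the pseudogenes ANXA2P1, ANXA2P2 and ANXA2P3. The transcription factor stem KLF had 5 of 12 higher and 0 lower (median 0.69, adjusted p = 0.0131), KLF2 (1.56 ± 0.19), KLF4 (1.69 ± 0.42), KLF6 (1.61 ± 0.23), KLF7 (0.88 ± 0.19) and KLF10 (0.97 ± 0.18). Among the 12 is KLF9-DT, which does not encode a transcription factor. Integrin alpha chains (stem ITGA) had 4 of 9 higher and 0 lower (median 0.80, adjusted p = 0.00812), and collagens (stem COL) 15 of 26 higher and 0 lower (median 1.24, adjusted p = 3.22e-10). These 2 stems overlap lists in the report, and KLF4 is also in its adipogenic and immediate early lists.

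Some stems of mitochondrial genes were lower, by smaller amounts. The mitochondrial ribosomal stem MRPL had 6 of 31 lower and 1 higher, MRPL17 (0.54 ± 0.16), with a median of -0.35 (adjusted p = 0.000271). The stem MRPS had 1 of 19 lower, MRPS7 (-0.62 ± 0.14), with a median of -0.29 (adjusted p = 0.00795). The cytochrome c oxidase stem COX had 4 of 16 lower and 0 higher (median -0.23, adjusted p = 0.00812), COX7C (-1.04 ± 0.19), COX11 (-0.72 ± 0.15), COX7B (-0.62 ± 0.19) and COX4I1 (-0.56 ± 0.12). The stem NDUFA had 1 of 10 lower, NDUFA3 (-1.19 ± 0.30; median -0.34, adjusted p = 0.0304). The mitochondrial stems NDUFB (median -0.13, adjusted p = 0.564), TIMM (-0.22, adjusted p = 0.540) and COQ (-0.11, adjusted p = 0.837) were not called.

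Of stems that are not mitochondrial, the chaperonin stem CCT had 1 of 8 lower, CCT4 (-0.48 ± 0.12; median -0.34, adjusted p = 0.0304). The NDUFA call was lost with arrays scaled to the same median (adjusted p = 0.0815) and the CCT call with that scaling (0.0849) and with quantile normalization (0.0664). The stem MCM, which holds replication genes and also MCM3AP and MCM3AP-AS1, had 2 of 10 lower, MCM3 and MCM4 (median -0.44, adjusted p = 0.00795). Both are also in the report's list for G1/S and DNA replication. MCM3 lost its call in 6 of the 8 omissions of an array (adjusted p up to 0.113) and MCM4 in 4 (up to 0.0936). On the low-ribosomal arrays neither was called (-0.70 and -0.60, adjusted p = 0.0684 and 0.168), nor without an intensity trend (0.101 and 0.0777) or with the GAPDH covariate (0.117 and 0.0782), nor MCM4 with the ribosomal covariate (0.0509). All directions of the called stems were the same with quantile normalization and with scaling to the same median.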
